A study of Mus musculus with 3 samples.

How the data were processed

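Genomic DNA of 3 medulloblastomas, tumours of the cerebellum, was compared with normal ear DNA of the same mouse by 2-colour array comparative genomic hybridisation. In this assay both DNAs compete for the same oligonucleotide probes, so the ratio of their dyes at a probe follows the relative copy number of its sequence. The mice were female, of a hybrid C3B6F1 background, and carried 1 disrupted copy of Ptch1, which encodes a receptor that restrains Hedgehog signalling. They had been exposed to X-rays on day 1 after birth at 0.1, 0.2 or 1.5 Gy. Each dose had 1 tumour on 1 array.

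Per the labels' protocols, purified DNA was cut with AluI and RsaI, labelled with Cy3 (normal ear) or Cy5 (tumour) and hybridised to Agilent oligonucleotide arrays. Agilent Feature Extraction 9.5.1 is named in the submitters' processing notes. The orientation of the dyes was the same on all 3 arrays, with no dye swap, so a value above 0 was taken as more tumour than normal signal. The background correction, dye normalisation, probe filter and log base are not given in the sources used here. The deposited table holds 1 log ratio per probe and array, for 14112 probes with feature numbers between 4 and 15740. Another 1625 feature numbers in that range are absent from the table. Missing values numbered 5, 14 and 23 on the 0.1, 0.2 and 1.5 Gy arrays, and 14075 probes had a value on all 3. No column of another sample was present (0 columns). The deposited values were read as log2 ratios. This reading rests on the values: a separate group of probes on 1 array had a mean of -0.89, near the -1 that loss of 1 of 2 copies gives on a log2 scale and far from the -0.30 it gives on a log10 scale. The reading assumes that this group is such a loss. On a log10 scale the same mean would be 0.127 times the normal signal, which the values alone do not exclude. The robust SD of 0.11 to 0.15 per array was also taken as that of log2 ratios. If the deposited values were log10 ratios, every log2 value given here would be larger by a constant factor, and log10 was run as an alternative. The array medians as deposited were -0.0087, 0.0021 and 0.0046, so the authors' values were already centred close to 0, by a step that is not stated.

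Probe positions and gene names were not used here, since none of the sources used here pairs the feature numbers with them. The planned segmentation, chromosome medians, Ptch1 locus, gene lists and values per gene were therefore not analysed here, and probes are reported as sets or, for 4 of them, by feature number. The share of probes in a set is not a share of the genome, since the spacing of the probes is unknown here.

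Each array was centred on its median. Probes at or beyond 0.5 log2 on either side were counted per array. Each probe's mean over the 3 tumours was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjusted p under 0.05), with the 3 mice as replicates. Dose was not fitted, so any effect of dose would be part of the spread between tumours. Pearson and Spearman correlations between arrays were computed across probes, which are not independent replicates. These choices, the size limits and the rule for naming probes (the most extreme means among limma's calls with 1 sign in all 3 tumours) were set before the data were examined. The plan also averaged the spots of 1 probe before limma. This was not done, since feature numbers alone do not show which spots share a probe. A count of probes here is therefore a count of array features, which may include repeated spots. At most 2 probes per direction were named, because they carry only numbers here.

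Discrete groups of probes were sought after the values had been seen. A Gaussian density with a bandwidth of 0.04 was laid over each array's ratios, and a group was called where the density had a minimum more than 0.3 from the median, a peak beyond it at least 1.5 times as high, and at least 20 probes past the minimum. The rule was tried on 14075 probes drawn from a normal distribution. Its spread and correlations were those of the probes within 0.5 on all 3 arrays. The rule recovered 99.4% of 40 probes lowered by 0.9 and 96.3% of 160 probes raised by 0.7. It took in 1.3 other probes per draw, and found a group in 0 of 20 draws without changes. The measured tails were heavier, with 37 probes at or below -0.5 in the 1.5 Gy tumour against 0.0844 for a normal distribution. The 1.3 and the 0 of 20 therefore do not estimate false groups on the measured arrays. In a simulation of the limma test on 14075 probes with independent noise, 100% of 100 probes raised by 0.6 and 100% of 100 lowered by 0.3 were recovered, with 15 unchanged probes called. That noise was not shared between arrays and had the same SD at every probe, whereas the measured arrays correlated across probes. The 15 therefore does not estimate the false calls on the measured arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

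Precision is limited by the number of arrays. An SD over probes covers the spread between probes of 1 array, not that between tumours, and values at different doses were compared side by side with no test. The alternatives were the centring (as deposited, or on the mode of the density), the size limit, the log base, limma's prior settings, probes with at least 2 values, each tumour left out in turn, Spearman's coefficient and, chosen after seeing the data, the bandwidth, removal of the part of each array predicted from the other 2 by least squares, and removal of the discrete groups.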

Results

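Tumour and matched normal DNA were compared in 3 irradiated mice, with 1 medulloblastoma at each of 0.1, 0.2 and 1.5 Gy. The question set by the design was where the tumour genomes had gained or lost DNA. Ratios were obtained for 14107, 14098 and 14089 probes in the 0.1, 0.2 and 1.5 Gy tumours. The robust SD of the log2 ratios over probes was 0.15, 0.12 and 0.11, so the 0.1 Gy array had the widest spread. There was 1 array per tumour and 1 tumour per dose, so no value of a single tumour has a replicate error, and dose, mouse and array cannot be told apart.

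In the 0.2 Gy tumour a discrete group of 33 probes, 0.23% of those on the array, lay far below the rest. Its mean log2 ratio was -0.89 ± 0.11 (SD over 33 probes). This is 0.538 times the normal signal on the log2 reading and would be 0.127 times on a log10 reading. The 33 probes ranged from -1.13 to -0.68 and were set apart by a density minimum at -0.66. The same probes lay close to 0 in the other tumours, at -0.034 ± 0.12 in the 0.1 Gy tumour and -0.075 ± 0.12 in the 1.5 Gy tumour (SD over 33 probes each). All 33 were lower in the 0.2 Gy tumour than in the 1.5 Gy tumour, by a mean of 0.82 ± 0.12 (SD), and all were lower than in the 0.1 Gy tumour.

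A larger discrete group of 179 probes, 1.27% of those on the array, lay above the rest in the 0.2 Gy tumour. Its mean log2 ratio was 0.70 ± 0.13 (SD over 179 probes), or 1.63 times the normal signal on the log2 reading, and 172 of its probes were at or above 0.5. The same 179 probes had a mean of 0.52 ± 0.17 in the 0.1 Gy tumour, or 1.43 times normal, where 177 were above 0 and 99 were at or above 0.5. Their mean in the 1.5 Gy tumour was 0.17 ± 0.13, or 1.13 times normal, with 165 above 0 and 2 at or above 0.5. On a log10 reading the signals would be 5.02, 3.30 and 1.49 times normal in the 0.2, 0.1 and 1.5 Gy tumours. As a set the group was also above the other probes in the 1.5 Gy tumour, although single probes overlapped. The 95% bootstrap interval of its mean over probes was 0.15 to 0.19, against a mean of -0.0037 for the rest. A positive mean there follows in part from choosing the probes on the 0.2 Gy array, since the 2 arrays also correlated among the other probes (Pearson's r = 0.612). The 0.2 Gy tumour exceeded the 0.1 Gy tumour at 173 of the 179 probes, by 0.18 ± 0.14 (SD), and the 1.5 Gy tumour at all 179, by 0.53. In the 0.1 Gy tumour, 7 of the 179 probes were below 0.2. No discrete group met the rule in the 0.1 or 1.5 Gy tumour taken alone. Both groups were defined on the 0.2 Gy array, which favours the extreme values there, and the rule was set after the values had been seen.

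**Figure D1:**
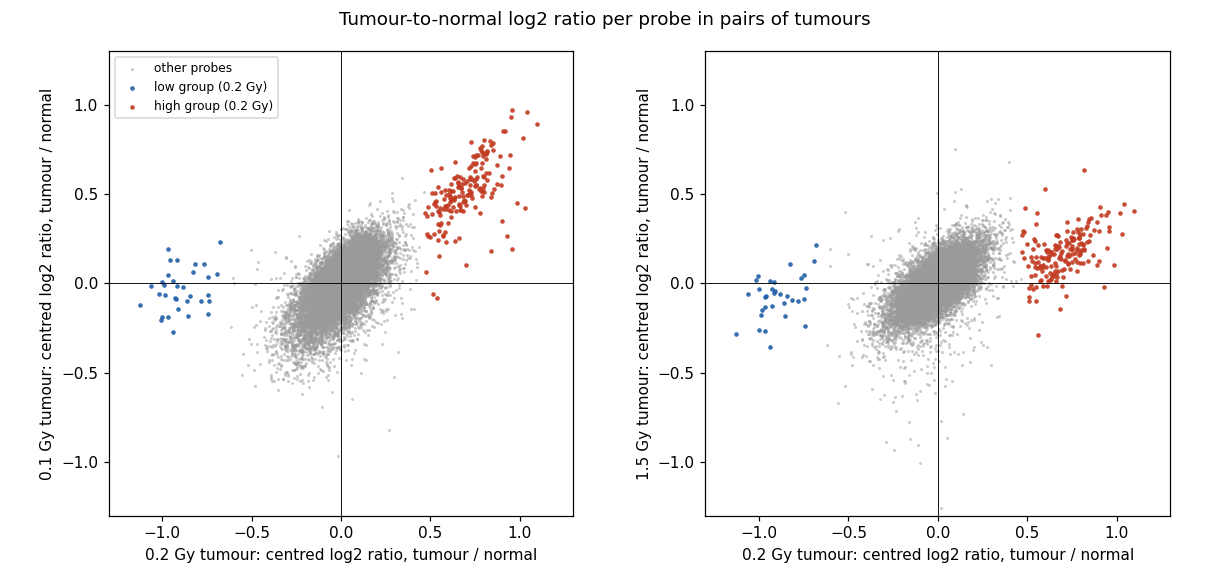
Each point is 1 probe, placed by its centred log2 ratio of tumour to normal DNA in the 0.2 Gy tumour (x axis) and in the 0.1 Gy (left) or 1.5 Gy tumour (right, y axis). The low group of 33 probes (blue) lies near -0.89 on the x axis and near 0 in the other tumours, and the high group of 179 probes (red) has means of 0.70, 0.52 and 0.17 in the 0.2, 0.1 and 1.5 Gy tumours.

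The 2 groups held most of the probes beyond the preset size of 0.5 log2 in the 0.2 Gy tumour. There, 42 probes were at or below -0.5, 33 of them in the low group, and 172 were at or above 0.5, all in the high group. The 0.1 Gy tumour had 41 probes at or below -0.5 and 102 at or above 0.5, and 99 of the 102 belonged to the high group. These 99 were also at or above 0.5 in the 0.2 Gy tumour, against 1.24 shared probes for independent lists of those lengths. The 2 arrays were not independent, since they also correlated outside the groups (Pearson's r = 0.639). The excess over 1.24 alone therefore does not show a shared change of DNA. The 1.5 Gy tumour had 37 probes at or below -0.5 and 7 at or above 0.5. A normal distribution with each array's robust SD would put 4.07, 0.262 and 0.0844 probes past 0.5 on each side in the 0.1, 0.2 and 1.5 Gy tumours.

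The low probes of the 0.1 and 1.5 Gy tumours formed a tail and no separate group. None of the 41 low probes of the 0.1 Gy tumour and none of the 37 of the 1.5 Gy tumour belonged to the low group of the 0.2 Gy tumour (0 in each). The low lists shared 1 probe between the 0.1 and 0.2 Gy tumours, 2 between the 0.2 and 1.5 Gy tumours and 3 between the 0.1 and 1.5 Gy tumours, where independent lists would share 0.122, 0.11 and 0.107. The correlation of the arrays across probes raises such overlaps, so they do not by themselves show shared losses. A single probe was at or below -0.5 in all 3 tumours. Of the 37 low probes of the 1.5 Gy tumour, 15 were also at or below -0.3 in the 0.1 Gy tumour and 6 in the 0.2 Gy tumour. Of the 41 in the 0.1 Gy tumour, 13 were at or below -0.3 in the 0.2 Gy tumour. Among all probes, 517 were at or below -0.3 in the 0.1 Gy tumour and 243 in the 0.2 Gy tumour. The overlaps at -0.3 therefore do not rank the likeness of the tumours.

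**Figure D2:**
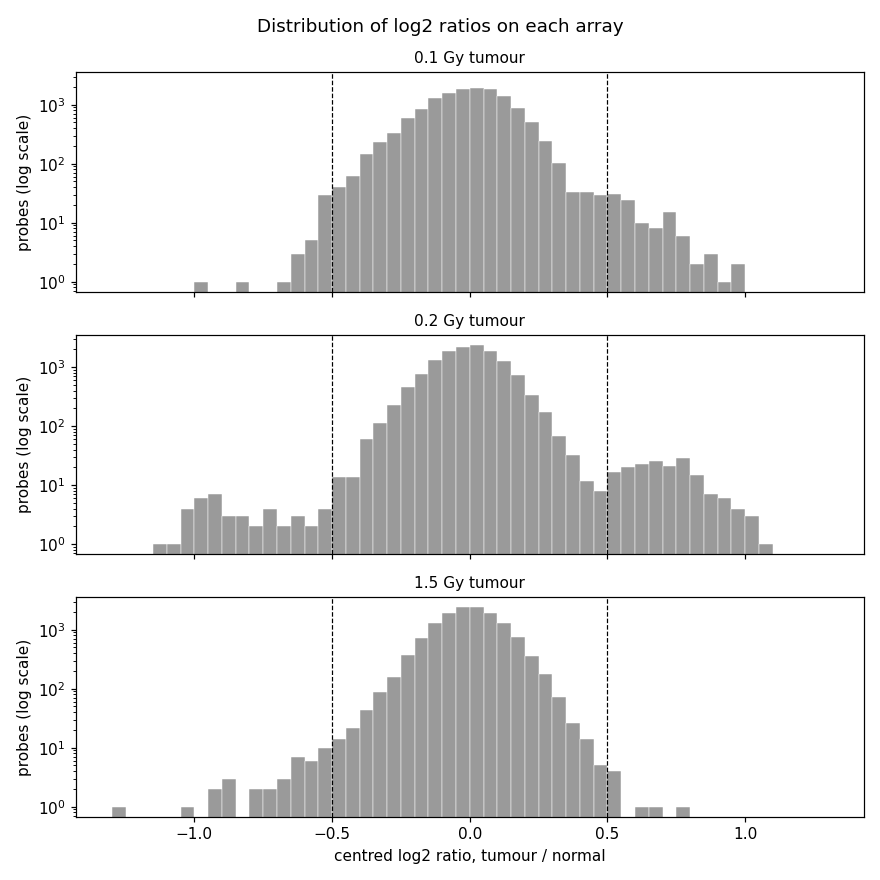
Histograms give the number of probes (log scale) by centred log2 ratio of tumour to normal DNA on each of the 3 arrays, with dashed lines at -0.5 and 0.5. The 0.2 Gy array has separate peaks on both sides, the 0.1 Gy array a shoulder above 0.5 that holds 102 probes, and the 1.5 Gy array a thin low tail of 37 probes.

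Over the 3 tumours together, limma called 1019 probes with a higher and 1191 with a lower tumour than normal signal (adjusted p under 0.05, 14075 probes tested). No array had its dyes swapped, so such a call may rest on a fixed offset of the probe rather than on a difference in DNA. At every called probe the sign was the same in 3 of 3 tumours, which a call over 3 arrays all but requires. This agreement is therefore not separate evidence. Most called probes had a small mean, with a median size of 0.20 among the higher and 0.21 among the lower probes. Only 64 higher and 5 lower probes had a mean of at least 0.5 in size. The high group supplied 161 of the 1019 higher probes, and the low group 4 of the 1191 lower ones. The highest mean was that of the probe with feature number 8165, at 0.81 ± 0.10 (SE, n = 3 tumours, limma adjusted p = 0.0106), followed by 35 at 0.80 ± 0.11 (limma adjusted p = 0.0114). The lowest were 15216 at -0.58 ± 0.045 (limma adjusted p = 0.0097) and 5689 at -0.57 ± 0.11 (limma adjusted p = 0.018). The counts depended on the tumours included. Without the 0.2 Gy tumour limma called 155 higher and 216 lower probes, without the 0.1 Gy tumour 326 and 394, and without the 1.5 Gy tumour 1191 and 1487. An exact sign-flip test of a single probe over 3 tumours cannot go below p = 0.25.

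The 3 profiles resembled each other across probes. Pearson's r was 0.673 between the 0.1 and 0.2 Gy tumours, 0.576 between the 0.2 and 1.5 Gy tumours and 0.448 between the 0.1 and 1.5 Gy tumours, and Spearman's rho was 0.647, 0.626 and 0.433. These are correlations across probes, which are not independent, and no p-value was computed. Each array had its own normal DNA, so the values share no control. With the low and high groups left out, r was 0.639, 0.612 and 0.427, so most of the correlation came from probes with small ratios. Within the high group r was 0.599 between the 0.1 and 0.2 Gy tumours, 0.454 between the 0.2 and 1.5 Gy tumours and 0.318 between the 0.1 and 1.5 Gy tumours. Each of these was below the value for the same 2 tumours with the groups left out. The other 2 arrays predicted 41.1%, 54.9% and 37.6% of the variance of the remaining probes in the 0.1, 0.2 and 1.5 Gy tumours.

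Set out by dose, the mean of the high group was 0.52, 0.70 and 0.17 at 0.1, 0.2 and 1.5 Gy, the mean of the low group was -0.034, -0.89 and -0.075, and the number of probes beyond 0.5 on the low side was 41, 42 and 37. Both groups were defined on the 0.2 Gy array, so their extreme means at 0.2 Gy follow in part from that choice. For the high group, the slope among the other probes predicts 0.52 in the 0.1 Gy tumour, as measured. The order of the counts beyond 0.5 depended on the limit, with 517, 243 and 205 low probes at 0.3 log2 and 99, 111 and 131 at 3 times the robust SD of each array. An effect of dose was not tested, since each dose had 1 tumour and a trend over 3 tumours would not separate dose from mouse.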

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

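Centring the arrays on the mode or leaving them as deposited kept all 6 counts beyond 0.5 log2 and both limma counts within 1.5 times. The limma counts also stayed within 1.5 times under limma's trend and robust settings and with probes that had at least 2 values. The bandwidth changed the high group from 179 to between 177 and 180 probes and left the low group at 33. The groups, their bandwidth, their removal, the removal of the shared part and the limit to probes within 0.3 on all 3 arrays were settings chosen after seeing the data. The counts moved with the size limit by construction. At 0.3 log2, 517 lower and 300.0 higher probes were counted in the 0.1 Gy tumour, 243 and 293 in the 0.2 Gy tumour, and 205 and 125 in the 1.5 Gy tumour. At 1 log2 these were 0 and 0, 6 and 4, and 2 and 0. At 3 times the robust SD, 99 lower and 139 higher probes were counted in the 0.1 Gy tumour, 111 and 211 in the 0.2 Gy tumour, and 131 and 59 in the 1.5 Gy tumour.

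If the values were log10 ratios, the 0.5 limit would take in 2289 lower and 1915 higher probes in the 0.1 Gy tumour, 1691 and 1535 in the 0.2 Gy tumour, and 1459 and 1415 in the 1.5 Gy tumour, and the low and high groups would have means of -2.97 and 2.33 log2. The limma counts do not depend on the log base. With the part predicted from the other 2 arrays removed, 10 lower and 28 higher probes passed 0.5 in the 0.1 Gy tumour, 38 and 31 in the 0.2 Gy tumour, and 29 and 14 in the 1.5 Gy tumour. The low group then had 36 probes, including all 33, while the high group no longer met the rule for a group and had a mean of 0.43, because its signal in the 0.1 Gy tumour is taken off by construction. Without the 2 groups, 41 lower and 3 higher probes were beyond 0.5 in the 0.1 Gy tumour, 9 and 0 in the 0.2 Gy tumour, and 37 and 5 in the 1.5 Gy tumour. In that setting limma called 1117 higher and 1485 lower of 13863 probes, more than the 1019 and 1191 with the groups kept.

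Leaving out 1 tumour gave between 155 and 1191 higher and between 216 and 1487 lower probes by limma, with the lowest counts without the 0.2 Gy tumour. These counts had the same order as Pearson's r between the 2 tumours kept. It was 0.448 without the 0.2 Gy tumour, 0.576 without the 0.1 Gy tumour and 0.673 without the 1.5 Gy tumour. The cause was not tested. The correlations kept their sign throughout. For the 0.1 and 0.2 Gy tumours r was 0.647 by Spearman, 0.639 without the groups and 0.595 over probes within 0.3 on all 3 arrays. For the 0.2 and 1.5 Gy tumours these were 0.626, 0.612 and 0.601, and for the 0.1 and 1.5 Gy tumours 0.433, 0.427 and 0.368. No paired analysis was possible because each dose had 1 tumour, and each tumour was already set against its own normal DNA within the array. The alternatives planned for segments, chromosomes, the Ptch1 locus, gene lists and 1 value per gene were not run. Signal over background was not examined, since the table holds only ratios.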

Other observations

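All tests below were chosen after the patterns had been seen, and the test on the spots next to a group's members was added once the distance between the members of the low group had been seen. The array was taken to have 82 spots per row, the spacing at which absent feature numbers recurred most often (r = 0.107 at 82).

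A first pattern is the high group of 179 probes shared by the 0.1 and 0.2 Gy tumours. A flaw that covers an area of the array is argued against, since the spots next to its members on the 0.2 Gy array had a mean of -0.0125 (95% bootstrap interval -0.020 to -0.0054) and its members lay no closer together than random sets. A probe offset acting alike on all 3 arrays is argued against as the whole cause: the slope among the other probes predicts 0.43 in the 1.5 Gy tumour, where the mean was 0.17 (0.15 to 0.19), although it predicts 0.52 in the 0.1 Gy tumour, as measured. The slope was fitted on probes outside the groups and extended past them, and its own error is not in the interval. An offset whose strength differs between arrays was not tested and stays open. On the log2 reading, the 0.2 Gy mean of 0.70 (0.68 to 0.72) lies above the 0.58 that 1 extra copy in every cell gives, yet after the 1.5 Gy values are taken off as a baseline it is 0.53 (0.51 to 0.55), below that limit. One extra copy and a larger gain therefore cannot be told apart, because it is open whether the 0.17 in the 1.5 Gy tumour is an offset of these probes or a gain in part of its cells. A gain of 1 region in 2 of the 3 tumours is a hypothesis that probe positions would test.

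A second pattern is the low group of 33 probes in the 0.2 Gy tumour alone. A probe offset alike on all arrays is argued against, since it predicts -0.68 in the 0.1 Gy tumour, where the mean was -0.034 (-0.073 to 0.0063). The prediction used a slope fitted on the other probes and extended past them. The members lay somewhat closer together on the array than random sets of 33, at a mean nearest distance of 9.53 spots against 11.9, the 2.49th percentile of 10000 sets, as a surface flaw would predict. The 233 spots next to them nevertheless had a mean of 0.0005 (-0.017 to 0.019), which argues against a flaw that covers an area, while flaws of single spots stay open. A candidate explanation is a loss of DNA in this tumour, whose depth stays open: the log2 reading was chosen partly because this group's mean lies near that of a loss of 1 of 2 copies, so it cannot count as evidence for such a loss, and on a log10 reading the signal would be 0.127 times normal. No biological explanation was tested.

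The last pattern is the correlation of the 3 profiles outside these groups, at r of at least 0.427. A trend over the array surface is argued against, since neighbouring spots of 1 array correlated by at most 0.009. An offset of the probes from the dyes or their sequence cannot be told apart from small differences shared by tumour against ear DNA, because no array had its dyes swapped and probe sequences were not used here. A limma call over these 3 arrays may therefore rest on a fixed property of the probe. For the 161 probes of the high group among the calls, an offset alike on all arrays was argued against above as the whole cause and stays open as a part of it. An offset whose strength differs between arrays stays open for them as well.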
